A study of Mus musculus with 5 samples.

How the data were processed

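The series holds 5 samples of total RNA from 46C Sox1-GFP mouse embryonic stem cells, extracted with Trizol and amplified into biotinylated cRNA with the Illumina TotalPrep kit, per the labels' protocols. Groups were taken from the sample labels: ESC (n = 2) and N2B27 48 hr (n = 3). Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

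The deposited signal intensity of each probe on each array is an average over beads on a linear scale, not normalized between arrays, and each comes with a detection p-value, per the file headers. The software was BeadStudio, per the submitters' processing notes, and its version is not given in the sources used here. Whether the authors subtracted background is not stated. The lowest signals lay between 38.5 and 40.7 on every array, so negative-control background was still in these intensities. A second deposited table holds the authors' normalized intensity values of the same arrays. Set against the first table, it ranked the probes of each array alike, shared a single distribution across arrays (sorted values differing by at most 1.35%), was linear and was neither background-subtracted nor centred. Its column medians were 65.2 to 65.3. No column of other samples was present. No chip or scan date is named in the files, so neither could be tested as a batch.

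From the intensities, background was corrected with limma 3.58.1 in R 4.3.3 by normexp, with the mean and SD of the negative controls inferred from the detection p-values (nec). The background mean was 57.0 to 60.0 and its SD 5.03 to 5.21. An offset of 16 was added, values were taken to log2 and the arrays were quantile normalized. Fold changes are therefore on the scale of log2(value + 16) and understate the change of dim genes. A probe entered the fit if its detection p was under 0.05 on at least 2 of the 5 arrays, which left 12605 of 25697 probes. The number of arrays limits the precision. The median standard error of a log2 change was 0.143, with 10.7 degrees of freedom of which 7.65 came from the moderation across probes. The median SD over genes was 0.0787 in ESC and 0.143 in N2B27 48 hr.

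Gene names came from the platform annotation, which lists 23978 probes with 1 symbol each and leaves 1719 unnamed here. Symbols were updated through the Entrez identifier in a RefSeq gene table of the assembly GRCm38.p6, where 23962 matched. The rest kept the annotation's symbol. That table served only for names and for which genes neighbour each other, and no coordinates are given because the files name no genome build. Of the unnamed probes 759 were tested, and 154 rose and 148 fell. A gene was represented by its probe with the highest mean log2 signal over the 5 arrays among those in the fit. In 777 genes at least 2 probes passed the test, and in 0 of these did they go opposite ways.

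The comparison was N2B27 48 hr against ESC in limma (lmFit and eBayes with a trend on mean log2 signal), two-sided, with Benjamini-Hochberg adjustment over all probes in the fit and a threshold of 0.05. Values after ± are standard errors of the log2 change unless an SD is named. Figures were drawn with matplotlib 3.10.9. Where a gene's probe was undetected on every array of a group, the fold is a lower bound, written as at least N-fold. It sets the mean of the group with signal against the mean, over the arrays of the other, of the higher of the probe's own value and the lowest value among detected probes of that array. The same floor and wording serve where a probe was undetected on only some arrays of a group. A bound applies to the probe, and a gene was called undetected only if all its probes were.

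Gene lists for pluripotency, germ layers, the signals withdrawn, metabolism, cell cycle, stress, chromatin, other cell types and controls were fixed before the data were examined. The 27 lists with at least 4 tested genes were compared with all other tested genes by limma's camera (two-sided, preset correlation 0.01, adjusted over the lists). Genes were named by a rule also fixed then. It takes the 8 largest rises and falls among genes detected on all arrays, the 4 largest lower bounds each way, up to 4 changed members of each list with up to 2 of the opposite direction, and a set of 20 key genes, and not all of these are printed. Of the key genes, the brachyury gene had no probe under its symbol. Other list members are named as examples that did not pass, or where a count was small, and were chosen after their values were seen. So were the members named with a log2 change alone.

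Alternatives fixed beforehand were no background correction, normexp without control information, offsets of 50 and 1, median scaling, cyclic loess, the authors' normalized values (log2, floor 16), no detection filter, detection p under 0.01 on 2 arrays, detection on all 5 arrays, leaving out each array, the replicate number as a block, no variance trend, array quality weights, thresholds of 2-fold or adjusted p under 0.01, the mean of all probes of a gene, an estimated correlation in camera, fry, and lists without shared genes.

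The steps were tested on simulated arrays with the background and spread of these samples, with 12701 probes in the fit. Of 67, 66 and 66 tested genes changed 1.5-fold, 2-fold and 4-fold, 22.4%, 50.0% and 60.6% were called, all in the right direction. With a simulated signal of at least 30 above background, 32 of 32 genes changed 4-fold were called and the median estimate was 0.921 of the true log2 change. With a lower signal 8 of 34 were called and the median estimate was 0.408 of it. Among 12490 unchanged probes 4 were called, which was 4% of 100 calls. A list of 15 genes raised 2-fold was recovered (adjusted p = 8.0e-25), and 0 of 27 unchanged lists were called. Only these seeded genes were changed, a far smaller share than the 3989 of 8828 genes called in the data. Recovery and error depend on that share, so these rates need not hold for the real comparison. The noise was also drawn for each probe separately, so the genes of a simulated list were not correlated. In the data the estimated correlation within a list ran from -0.142 (primitive streak and mesoderm) to 0.451 (glycolysis), and was 0.412 for naive pluripotency. The simulated lists therefore cannot show how often camera calls an unchanged list whose genes are correlated.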

Results

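Gene expression was measured on single-colour Illumina mouse bead arrays, 1 array per sample, in 5 samples of the 46C mouse embryonic stem cell line, which carries a green fluorescent protein reporter for the neural gene Sox1. In the ESC group (n = 2) the cells were kept pluripotent without feeder cells or serum in N2B27, a defined medium, with the cytokine LIF, BMP and 100 nM of the FGF receptor inhibitor PD173074. In the N2B27 48 hr group (n = 3) cells of the same line were washed, replated and grown for 48 hr in N2B27 with none of these additions. The labels call the first state pluripotent and the second competent to respond to differentiation signals, so the comparison asks which transcripts accompany the passage from one to the other. Each array held 25697 probes, of which 10806 to 12218 (42.1% to 47.5%) were detected above background. The mean signal was 264 and 242 on the ESC arrays and 187, 235 and 250 on the N2B27 48 hr arrays, so that N2B27 48 hr replicate 1 was the dimmest. After normalization, Pearson's r across probes was 0.995 within ESC, 0.986 to 0.992 within N2B27 48 hr and 0.915 to 0.927 between the groups.

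After 48 hr in N2B27 the regulators that mark naive embryonic stem cells had lost most of their signal, and genes of the postimplantation epiblast had gained it. Nanog, a homeobox factor of the pluripotency network, was 33.6-fold lower (log2 change -5.07 ± 0.128 SE, adjusted p = 7.0e-10, n = 2 and 3). Pou3f1, a POU factor of the epiblast and early neural lineage, was 44.5-fold higher (5.47 ± 0.106, adjusted p = 1.7e-10). Fgf5, the classical epiblast marker, was at least 30.7-fold higher (adjusted p = 4.2e-10) and Dnmt3b, a de novo DNA methyltransferase, was 13.3-fold higher (3.73 ± 0.0662). Pou5f1, which encodes Oct4, fell by only 0.44 ± 0.0849, or 1.36-fold.

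Of 8828 genes tested, 3989 (45.2%) changed at an adjusted p under 0.05, 2100 of them upward and 1889 downward. Changes of at least 2-fold were fewer upward than downward, with 462 genes that rose and 660 that fell. At 4-fold or more the counts were 89 and 197, and at 8-fold or more 29 and 61. By all of their probes, 153 of the genes that rose were detected on no ESC array while the probe tested was detected on all 3 N2B27 48 hr arrays, and 264 of those that fell were detected on both ESC arrays and on no N2B27 48 hr array. The first principal component, which separated the groups, held 87.4% of the variance. Without ESC replicate 1 or 2, the remaining ESC array was assumed to vary like the other group. Genes detected on ESC arrays alone then could not reach the 2 arrays of the detection filter. The genes tested numbered 8294 without ESC replicate 1 and 8350 without ESC replicate 2. Calls were lost widely in these fits, so such a loss is not particular to the genes named for it below. Scaling each array to its median instead of quantile normalization moved the median log2 change of all genes from 0.0488 to -0.106. With it 29.7% of 2562 changed genes rose, against 52.6% of 3989. The array median was taken over all probes, most of them undetected on each array, so this scaling aligned the level of undetected probes.

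**Figure D1:**
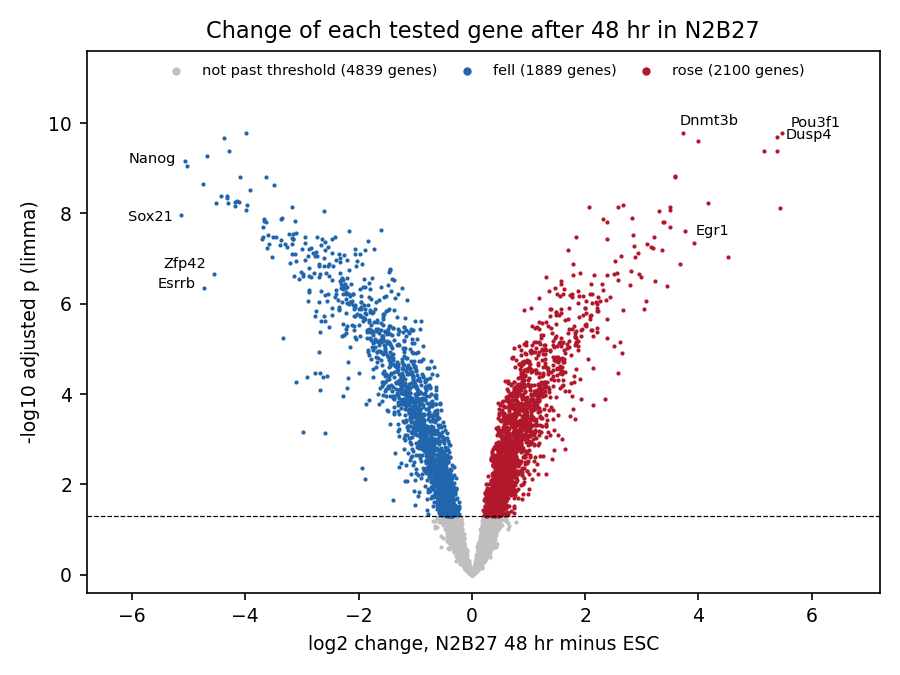
Log2 change (N2B27 48 hr minus ESC, horizontal) against -log10 of limma's adjusted p (vertical) for the 8828 genes tested, 1 point per gene, with 2100 genes that rose in red, 1889 that fell in blue and 4839 not past the threshold in grey. The dashed line marks an adjusted p of 0.05, and Nanog at -5.07 and Pou3f1 at 5.47 lie near the edges of the range.

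Among genes detected on all arrays, the 8 largest rises were those of Pou3f1, Esrp1, Dusp4, Zyx, Egr1, Dnmt3b, Igsf9 and Acsl5. Esrp1, an epithelial splicing regulator, was 41.9-fold higher (5.39 ± 0.126). Dusp4, a phosphatase that acts on MAP kinases, was 41.8-fold higher by its brightest probe (5.38 ± 0.112). All 3 of its probes rose, the others at least 9.91-fold and 2.53-fold. Zyx, which encodes the focal adhesion protein zyxin, rose by 3.998 ± 0.0873. Igsf9, an immunoglobulin superfamily member, and Acsl5, an acyl-CoA synthetase, rose by 3.59 ± 0.102 and 3.58 ± 0.0993. The 8 largest falls were those of Sox21, Nanog, Esrrb, Tfap2c, Zfp42, Slc25a20, Aard and Klf2. Sox21, an SRY-box factor, was 35.1-fold lower by its brighter probe, and Tfap2c, an AP-2 factor of trophectoderm and germ cells, was 25.5-fold lower. Slc25a20, the mitochondrial carnitine and acylcarnitine carrier, was 20.9-fold lower by its brighter probe and at least 10.8-fold by the other. Aard was 19.4-fold lower. Among genes with no probe detected in one group, Zfp608, the carbonic anhydrase gene Car14 and the amino acid transporter gene Slc7a7 rose at least 11.9-fold, 9.65-fold and 9.59-fold. Spic, an ETS factor, 2210409E12Rik, the junctional adhesion gene Jam2 and the basement membrane gene Nid1 fell at least 21.4-fold, 16.5-fold, 15.98-fold and 14.1-fold. By other probes the bounds were smaller, 7.55-fold for Slc7a7, 3.70-fold for Spic and 11.5-fold, 6.09-fold and 5.04-fold for Jam2. By the probe that represents each gene, all adjusted p-values in this paragraph were under 0.05, the largest being that of Esrrb and Car14 (4.6e-07 and 4.1e-07).

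Naive pluripotency genes fell together. Of 14 tested, 12 fell, 1 rose and 1 did not pass the test, with a median log2 change of -3.86. Beside Nanog, the nuclear receptor gene Esrrb was 26.7-fold lower (-4.74 ± 0.298), Zfp42, which encodes the zinc finger protein Rex1, was 23.4-fold lower (-4.55 ± 0.260), and the AKT coactivator gene Tcl1 was at least 29.0-fold lower by its brighter probe, and at least 7.53-fold lower by the other, which was still detected on 1 N2B27 48 hr array. Krüppel-like factor genes fell likewise, Klf2 17.1-fold (-4.10 ± 0.117) and Klf4 at least 13.6-fold by its brightest probe. The other probes of Klf4 fell at least 10.5-fold and 3.87-fold. Gbx2, a homeobox gene also counted among LIF-responsive genes, rose (1.82 ± 0.156), and Nr0b1 did not pass (adjusted p = 0.428). The list ranked below the other genes tested (camera adjusted p = 1.0e-08), and its adjusted p = 0.314 with an estimated correlation between its genes.

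Epiblast and primed pluripotency genes rose. Of 12 tested, 9 rose, 0 fell and 3 did not pass, with a median of 1.69 (camera adjusted p = 1.6e-06, and adjusted p = 0.306 with an estimated correlation). Grhl2, a grainyhead factor of epithelia, rose at least 6.92-fold (adjusted p = 1.9e-07), Sall2 by 2.53 and Zic2 by 1.52. Otx2, a homeobox gene of the epiblast and anterior brain, rose from a high ESC level (0.43 ± 0.109, adjusted p = 0.00867). Its call was lost without ESC replicate 2 (0.33, adjusted p = 0.124) and under median scaling (0.23, adjusted p = 0.596).

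Genes of general pluripotency went both ways, with 5 that rose and 7 that fell among 13 tested (median -0.44, camera adjusted p = 0.387). Under median scaling 2 rose and 6 fell, and under cyclic loess 3 and 7. Sox2, the SRY-box partner of Oct4, was 4.51-fold lower by its brighter probe (-2.17 ± 0.120, adjusted p = 1.8e-07) and lower by the other. The Nodal coreceptor gene Tdgf1 fell at least 4.60-fold by its brighter probe (adjusted p = 1.1e-04) and at least 1.32-fold by the other, and Fgf4 fell by 1.69 ± 0.139. The chromatin factor gene Utf1 (1.99 ± 0.142) and Lin28a (1.60 ± 0.185), an RNA-binding inhibitor of let-7 processing, rose. The fall of Pou5f1 passed the test with both of its probes (-0.44 and -0.30, adjusted p = 0.00157 and 0.0152), but not under median scaling (-0.62, adjusted p = 0.0613). Of the 20 key genes fixed before the data were examined, 15 were tested, and 4 rose and 10 fell.

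**Figure D2:**
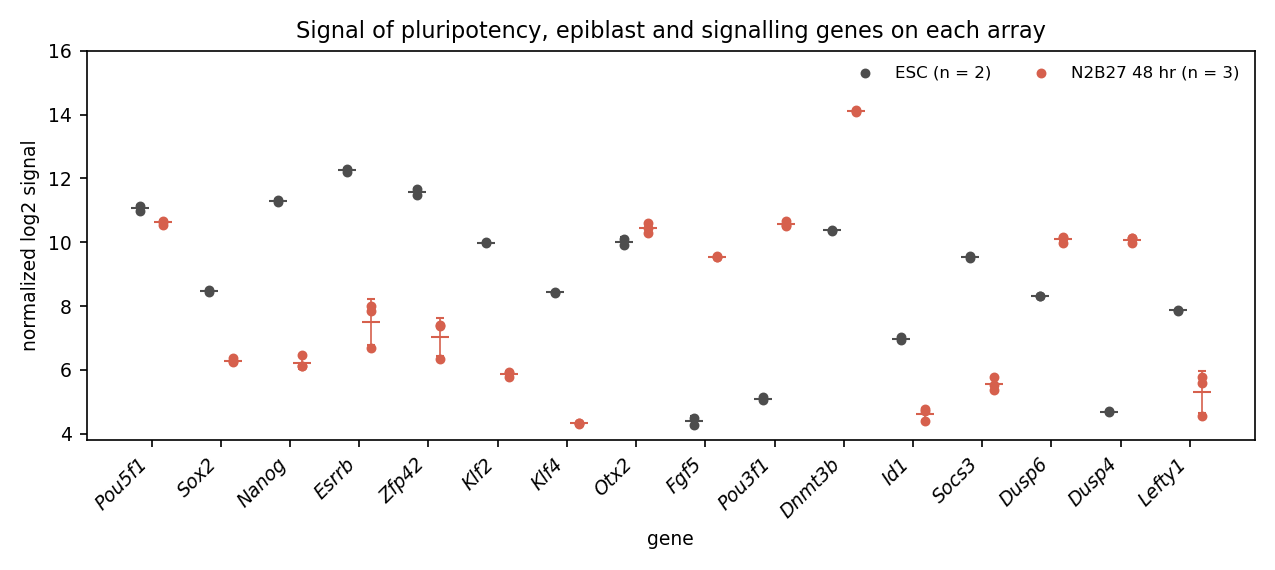
Normalized log2 signal (vertical) of 16 genes (horizontal) on each ESC array (grey, n = 2) and each N2B27 48 hr array (red, n = 3), with horizontal ticks for group means and bars for ± 1 SD. Pou5f1 lies near 11 in both groups, while Nanog goes from a mean of 11.30 to 6.23 and Dnmt3b from 10.38 to 14.11.

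Targets of the signals removed or released at replating also moved. LIF-STAT3 targets fell, with 9 lower, 1 higher and 2 not past the test among 12 (median -1.57, camera adjusted p = 0.000896, and adjusted p = 0.314 with an estimated correlation). Socs3, the feedback inhibitor of this pathway, was 15.8-fold lower (-3.98 ± 0.144), Klf5 fell by 2.68 ± 0.225 and Stat3 itself by 2.21 ± 0.269. Targets of the ERK pathway, which acts below the FGF receptor, rose as a list (camera adjusted p = 0.0126, and adjusted p = 0.314 with an estimated correlation), with 6 higher, 1 lower and 6 not past the test among 13. Beside Dusp4, the immediate early gene Egr1 was 13.6-fold higher (3.77 ± 0.159), the ETS factor gene Etv4 5.18-fold higher, the inhibitor gene Spred1 4.12-fold higher and the ERK phosphatase gene Dusp6 3.44-fold higher (1.78 ± 0.0953), while Ier3 fell by 1.43 ± 0.157. The median of the ERK list was 0.22 and its mean 1.22, since Fos, Ccnd1 (0.17) and Etv5 (0.21) were among the members that did not pass. Of 6 BMP-SMAD targets 4 fell and 2 rose (median -1.23, camera adjusted p = 0.165). The median ran from -2.11 to -0.195 over the alternatives, the latter without the detection filter. The rise of the homeobox gene Msx1, at least 1.60-fold, did not pass without ESC replicate 1 or 2 (adjusted p = 0.0629 and 0.150). Among the inhibitors of differentiation, Id1 was at least 4.80-fold lower (adjusted p = 8.3e-07) and Id4 at least 2.85-fold lower. Id2 was at least 4.78-fold lower by its brighter probe, whereas the other did not pass (adjusted p = 0.0658), and Id3 was 2.26-fold higher.

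In the Nodal-Activin pathway 4 of 7 genes fell and 2 rose (median -2.28, camera adjusted p = 0.165). The median ran from -3.16 to -0.070 over the alternatives. Adjusted over the list alone, 4 fell and 3 rose, and under median scaling 4 fell and 1 rose. Lefty2, detected on 1 N2B27 48 hr array, was at least 19.6-fold lower (adjusted p = 5.8e-09), the ligand gene Nodal at least 7.497-fold lower (adjusted p = 2.2e-07) and the antagonist gene Lefty1 at least 5.80-fold lower (adjusted p = 4.0e-05), while the SMAD partner gene Foxh1 was 2.15-fold higher. The rise of Skil did not pass without ESC replicate 1 or 2 or N2B27 48 hr replicate 2 (adjusted p = 0.107, 0.161 and 0.0904). Under median scaling both the BMP and the Nodal list passed the test (adjusted p = 0.00170 and 7.1e-06). Among 4 Wnt targets, Lef1 rose at least 2.89-fold and the Wnt inhibitor gene Notum fell at least 7.27-fold, with a median of 0.31, a mean of -0.098 and opposite directions from camera (up, adjusted p = 0.684) and fry (down, adjusted p = 0.187). In the retinoic acid response, 1 of 6 genes rose and 3 fell (median -0.41, camera adjusted p = 0.356), with Crabp2 4.25-fold higher, Meis2 9.41-fold lower and Meis1 at least 2.00-fold lower.

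Markers of committed lineages were mostly below detection or lower. Of 18 neural ectoderm genes with a probe only 4 were tested, and 2 of them rose (median 0.29, or 0.17 with the bound of Dll1 in place of its change, camera adjusted p = 0.428). These were the Notch ligand gene Dll1 (at least 1.24-fold, adjusted p = 0.00938) and Irx3 (0.55 ± 0.165, adjusted p = 0.0194). Without ESC replicate 1 or 2 their adjusted p-values were 0.132 and 0.0800 for Dll1 and 0.174 and 0.0854 for Irx3. The probes of Sox1, Pax6 and Gata6 were detected on 0 arrays and that of Cdx2 on 1. A probe below background does not show that a gene is silent, since the probes of Pgk1, a glycolytic enzyme gene in common use as a control, and Dnmt3a also failed the filter. Of 4 primitive streak and mesoderm genes tested, 0 rose and 2 fell (median -0.27, camera adjusted p = 0.261). The homeobox gene Gsc fell at least 5.31-fold, and Evx1 fell by 0.59 ± 0.144, with an adjusted p of 0.0805 without ESC replicate 1 and 0.0677 without ESC replicate 2. Mixl1 did not pass (adjusted p = 0.774).

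Endoderm genes fell as a list, with 6 lower, 1 higher and 4 not past the test among 11 (median -0.56, camera adjusted p = 0.00717, and adjusted p = 0.314 with an estimated correlation). The size of that median depends on which dim members are tested, and it ran from -2.06 to -0.037 over the alternatives, the latter without the detection filter. The largest falls were those of matrix genes, the basement membrane collagen genes Col4a2 (12.1-fold lower) and Col4a1 (8.68-fold lower), the laminin gene Lama1 (8.24-fold lower) and Sparc (4.16-fold lower), which many cell types secrete. Among transcription factors of that list, Hhex fell by 1.29, while Sox7 and Hnf4a did not pass (adjusted p = 0.247 and 0.802). The endocytic adaptor gene Dab2 rose by 0.93 ± 0.203, with an adjusted p of 0.0528 without ESC replicate 2. Of 8 trophectoderm genes, 5 fell and 2 rose (median -0.78, camera adjusted p = 0.196, and 0.0295 under median scaling). Tfap2c and Tead4 (3.92-fold lower by its brightest probe) were among those that fell, and the keratin genes Krt8 (4.24-fold higher) and Krt18 (at least 3.61-fold higher) rose. Of the 3 probes of Tead4, 2 fell and the other did not pass (adjusted p = 0.381). Hox genes were dim, with 13 of 35 that have a probe tested. Of these, 6 fell and 0 rose (median -0.31, camera adjusted p = 0.0340, and adjusted p = 0.314 with an estimated correlation), among them Hoxc6 and Hoxc13, at least 1.79-fold and 1.91-fold lower. The Hox call was lost in 9 of 18 alternatives tested with camera at the preset correlation. The adjusted p-values were 0.0545 without N2B27 48 hr replicate 2 and 0.0730 without N2B27 48 hr replicate 3. Without ESC replicate 1 or 2 the median was -0.068 and -0.042. With 1 ESC array left, a gene detected on ESC arrays alone cannot reach the 2 arrays of the filter. Those fits therefore tested a smaller list and do not bear on such genes. Of the 13 tested, 8 were detected on both ESC arrays and on 0 N2B27 48 hr arrays, and without the detection filter the Hox median was -0.0067. Genes of the 2-cell-like state fell, 3 of 4 tested (median -1.51, camera adjusted p = 0.0254, and adjusted p = 0.339 with an estimated correlation). These were Zscan4c, Tcstv3 and Tcstv1, at least 6.80-fold, 2.35-fold and 2.08-fold lower, and without N2B27 48 hr replicate 3 the list had an adjusted p of 0.0515. Its median ran from -3.10 to -0.13 over the alternatives, the latter without the detection filter. Of 8 such genes with a probe 4 were tested. The 3 that fell were detected on both ESC arrays and on 0 N2B27 48 hr arrays, so the change itself helped decide which were tested.

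Of 14 markers of fibroblasts, which were not used as feeders per the labels, 4 were tested, and 3 rose and 1 fell (median 2.07, camera adjusted p = 0.0767). Thy1, a surface glycoprotein gene, rose 4.92-fold, and Fbln2 fell at least 1.48-fold. The proteoglycan gene Dcn rose at least 2.84-fold by its brighter probe and at least 1.22-fold by the other. For the smooth muscle actin gene Acta2 the brightest of 4 probes rose at least 18.3-fold, while the others, detected on 1 or 2 ESC arrays, rose at least 3.05-fold, rose by 0.86, and did not pass (adjusted p = 0.233). The list passed under median scaling and cyclic loess (adjusted p = 3.3e-05 and 0.0432). Its median ran from -0.012 to 3.18 over the alternatives, so its size depends on which members are tested and on the processing. Among epithelial and mesenchymal genes 4 of 12 rose and 3 fell (median 0.30, camera adjusted p = 0.428), or 5 and 3 adjusted over the list alone. Of the epithelial genes that passed, the tight junction gene Cldn6 was 6.38-fold higher, Cldn3 at least 1.77-fold higher and Cdh1 higher by 0.62. The integrin gene Itgb4 was at least 2.89-fold lower by its brighter probe and at least 1.36-fold by the other. Of the mesenchymal genes, the repressor gene Zeb1 was 4.59-fold lower and Vim lower by 0.86, while the protease gene Mmp2 was 2.46-fold higher. The list pools both kinds, so its median and camera p cannot show opposed changes. This split by kind was made after the values were seen and was not tested.

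Cholesterol biosynthesis genes rose, 9 of 12 tested with 0 lower (median 0.75, camera adjusted p = 0.000387, and adjusted p = 0.314 with an estimated correlation). The enzyme genes Lss, Mvd, Cyp51 and Msmo1 were 3.53-fold, 2.29-fold, 2.28-fold and 2.04-fold higher, while Idi1 (0.09) did not pass and Insig1 did not by its brightest probe (0.08) but rose by the other 2. Under median scaling 6 of these genes rose. Glycolysis genes went both ways, with 7 of 16 higher and 3 lower, a median of 0.12, a mean of -0.043 and a camera direction upward (adjusted p = 0.543). Under median scaling 3 rose and 4 fell with a median of -0.095, and under cyclic loess 6 rose and 3 fell with a median of -0.022. The glucose transporter genes moved apart, Slc2a3 lower (-2.58 ± 0.119) and Slc2a1 higher (1.18 ± 0.0794), as did the phosphofructokinase genes Pfkp (-2.91 ± 0.330) and Pfkm (1.04, with 2 of its 3 probes rising). The hexokinase gene Hk2 was 2.35-fold lower and Pdk1, a kinase that restrains pyruvate dehydrogenase, 4.40-fold higher. Of 20 oxidative phosphorylation genes 0 rose and 5 fell, or 4 adjusted over the list alone (median -0.026, camera adjusted p = 0.226), the cytochrome oxidase gene Cox5a by the most (-1.14 ± 0.0776). Under cyclic loess 9 fell (median -0.149) and under median scaling 3 (median -0.225). The fall of Uqcrb did not pass without ESC replicate 2 (adjusted p = 0.0611), nor that of Cox7a2 without ESC replicate 1 or 2 or N2B27 48 hr replicate 1 or 2 (0.331, 0.107, 0.0925 and 0.118).

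Cell cycle genes changed little. For S phase, 4 of 15 genes rose and 2 fell (median 0.13, camera adjusted p = 0.388), and under median scaling 1 rose and 0 fell with a median of -0.098. The cyclin gene Ccne2 was 1.72-fold higher. Without ESC replicate 1 the rise of Rrm1 and the falls of Ung and Cdc6 did not pass (adjusted p = 0.0555, 0.0946 and 0.226), nor did that of Cdc6 without ESC replicate 2 or N2B27 48 hr replicate 1 or 2 (0.173, 0.0695 and 0.0930). For the G2 and M phases, 0 of 11 rose and 2 fell, or 0 adjusted over the list alone (median -0.070, camera adjusted p = 0.705), and under median scaling 0 fell. The genes that fell were Aurka (-0.34 ± 0.0984) and Cdk1 (-0.26 ± 0.0921), and without ESC replicate 1 or 2 their adjusted p-values were 0.0998 and 0.116 for Aurka and 0.108 and 0.322 for Cdk1. Without N2B27 48 hr replicate 1 or 2 that of Cdk1 was 0.0664 and 0.0598. Of 11 p53 targets 1 rose and 3 fell (median -0.14, or -0.39 under median scaling, camera adjusted p = 0.165), among them the cell cycle inhibitor gene Cdkn1a, 2.21-fold lower. Genes of unfolded protein and amino acid stress went both ways, with 7 of 14 higher and 3 lower (median 0.34, camera adjusted p = 0.388), or 4 and 3 with a median of 0.14 under median scaling. Chac1, a glutathione-degrading enzyme gene, was 7.30-fold higher and the serine synthesis gene Phgdh 2.39-fold higher, while the asparagine synthetase gene Asns was 2.04-fold lower.

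Among genes of DNA methylation and Polycomb 3 of 12 rose and 6 fell (median -0.22, or -0.45 with 2 and 5 under median scaling), with camera downward (adjusted p = 0.428) and fry upward (adjusted p = 0.0765). Dnmt3b rose, while its catalytically inactive partner Dnmt3l was 3.68-fold lower (-1.88 ± 0.469) with a wide spread in N2B27 48 hr (SD 1.17). Without N2B27 48 hr replicate 3 the change of Dnmt3l was -1.20. That replicate was also the lowest of its group for Esrrb, Zfp42 and Pfkp (SD 0.717, 0.608 and 0.791), but not for every gene that fell, being the highest for Sox21. The Polycomb genes Eed (-1.002 ± 0.107), Suz12 (-0.92) and Ezh2 (-0.34, by 1 of its 2 probes) fell, and the glycosylase gene Tdg was 2.20-fold higher. Of 8 germline genes 2 rose and 2 fell, or 2 and 3 adjusted over the list alone, 0 and 3 under median scaling and 1 and 4 under cyclic loess (median -0.074, camera adjusted p = 0.543), with the RNA-binding gene Dazl 2.10-fold lower. The other 3, Taf7l, Stk31 and Stag3, did not pass without ESC replicate 1 (adjusted p = 0.123, 0.176 and 0.1075) or ESC replicate 2 (0.1697, 0.0839 and 0.149), nor did Taf7l and Stag3 without N2B27 48 hr replicate 2 (0.0886 and 0.0688) or Taf7l without N2B27 48 hr replicate 3 (0.0586). Of 8 control genes 3 rose and 1 fell (median 0.21, camera adjusted p = 0.428). The glucuronidase gene Gusb rose by 0.85 ± 0.104, which under median scaling did not pass (0.62, adjusted p = 0.0928), the transferrin receptor gene Tfrc fell by 0.54 ± 0.0876, and Actb had a log2 change of -0.06. Under median scaling 0 of the control genes rose and 1 fell. The rise of Tbp did not pass without ESC replicate 1 or 2 (adjusted p = 0.0681 and 0.178), nor that of Ywhaz without ESC replicate 2 (0.0778).

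**Figure D3:**
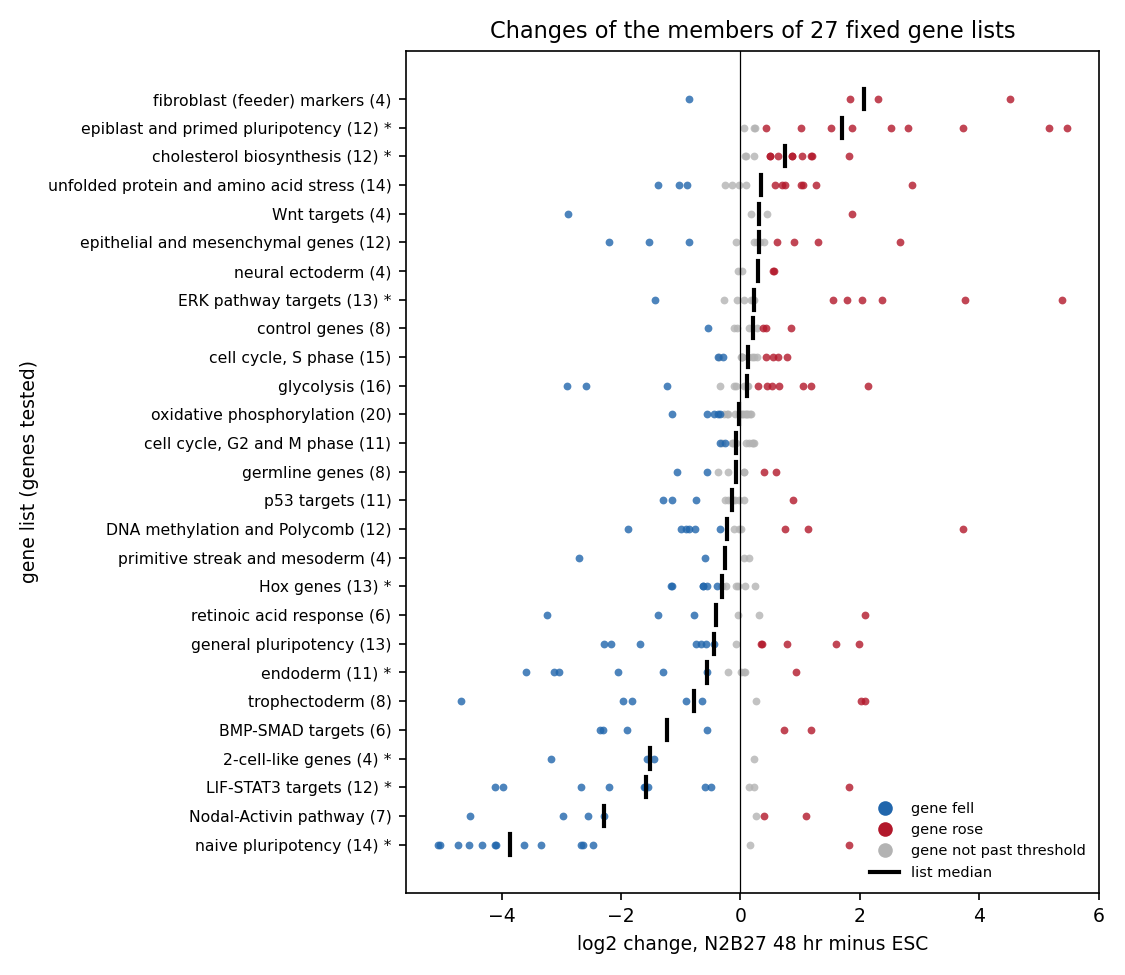
Log2 change (N2B27 48 hr minus ESC, horizontal) of each tested member of 27 gene lists (vertical, number tested in brackets), 1 point per gene, with black bars at list medians and asterisks at the 8 lists with a camera adjusted p under 0.05. Medians run from -3.86 for naive pluripotency to 2.07 for the fibroblast markers, which had 4 genes tested and did not pass. The median of these markers ran from -0.012 to 3.18 over the alternatives.

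Of the 27 lists, 3 rose and 5 fell with camera at a preset correlation of 0.01. With the correlation estimated for each list 0 passed after adjustment, 3 had an unadjusted p under 0.05 and the smallest of these was 0.0113. By fry, which asks whether the genes of a list moved on balance one way and makes no comparison with other genes, 21 lists passed. The counts of members that rose and fell were the same when adjusted over the list alone for 22 of the 27 lists, and the other 5 are given above. With 2 arrays against 3 there are 10 splits, so a permutation of a single value cannot reach 0.05, and the p-values of single genes rest on limma's pooling of the spread across probes.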

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

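Of the alternatives here, those that joined median scaling with leaving out an array were chosen after the results were seen. Signal over background limits what dim probes show. In none of the 19 refits of all genes did a gene called in the comparison turn to the opposite call. The count of changed genes (3989) moved by over 1.5 times under median scaling (2562, with 760 that rose), with a 2-fold minimum (1122, with 462 up and 660 down, by construction) and without 1 array (2340 to 4234 changed, 1272 to 2229 up, 1068 to 2005 down, lowest with a lone ESC array). The share that rose was 29.7% under median scaling and 45.2% when that scaling left out N2B27 48 hr replicate 1, and 35.4%, 27.02%, 27.6% and 22.9% when it left out ESC replicate 1, ESC replicate 2, N2B27 48 hr replicate 2 or N2B27 48 hr replicate 3. The replicate block gave 4354. The labels tie the numbers to no shared batch, and only 2 are common to both groups. The deviations of replicates 1 and 2 correlated at -0.073 across groups. That shows no pairing, but with so few arrays it cannot exclude a batch shared by a number. Chip as a block was not run, since the files name none.

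The 8 called lists became 0 with an estimated correlation, at unchanged medians of -3.86 (naive pluripotency), 1.69 (epiblast), -0.56 (endoderm), 0.22 (ERK), -1.57 (LIF-STAT3), -0.31 (Hox), 0.75 (cholesterol) and -1.51 (2-cell-like). Over all alternatives these medians ran from -4.55 to -2.77, 0.718 to 2.49, -2.06 to -0.037, 0.148 to 0.995, -2.08 to -0.764, -0.954 to -0.0067, 0.540 to 0.761 and -3.10 to -0.134, in that order, so their sizes depend on the processing while their signs stayed. The estimated correlation was 0.412 for naive pluripotency, 0.181 for 2-cell-like, 0.115 for LIF-STAT3 and 0.057 for cholesterol. For epiblast, endoderm, ERK and Hox it was -0.066, -0.044, -0.0031 and 0.0092, below the preset 0.01. In these last lists the loss of the call therefore does not show that their genes are correlated. Fry, which compares with no other genes, called 21. The 2-cell-like list was lost without N2B27 48 hr replicate 3 (-1.49, with -1.61 to -1.49 over the arrays left out that leave 4 genes). Hox genes were lost under median scaling (-0.33), cyclic loess (-0.32), no filter (-0.0067), the filter at 0.01 (-0.62), the replicate block (-0.34) and with 4 of the 5 arrays left out in turn (-0.37 to -0.042). Where an ESC array was left out, Hox genes detected on ESC arrays alone could not pass the filter, so the list was smaller. Lists gained were BMP, Nodal, trophectoderm and fibroblast under median scaling, fibroblast under cyclic loess, BMP without the filter, and Nodal and fibroblast under the block. Of 2197 values of 126 named genes over 18 settings, 73 lost their call and 0 reversed, and 1 sign turned in a gene called in neither fit. A gene that failed the filter under a setting has no value there and is not counted as lost. Many of the named genes were chosen for the size of their change in these data, so losses and reversals were unlikely from the start. The causes were not tested.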

Other observations

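The test of the collagen probes, the signal-trend test of neighbouring genes and median scaling with an array left out were chosen after the results they bear on were seen. The genes of the next paragraph were chosen after their values were seen, from the table of all genes.

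Among genes outside the fixed lists, Fzd7 was 11.3-fold higher (3.50, adjusted p = 7.3e-09), Fzd2 at least 4.42-fold higher (adjusted p = 1.3e-06) and Fzd10 7.98-fold lower (adjusted p = 6.1e-08) after 48 hr in N2B27. These are 3 of the Wnt receptor genes, and the others were not examined as a group. The actin genes Acta1 and Actc1 rose at least 6.35-fold and 3.60-fold beside Acta2 (adjusted p = 1.3e-06 and 9.2e-07). The chemokine gene Cxcl12 rose at least 35.8-fold by its brightest probe (adjusted p = 7.5e-09), which was detected on 0 ESC arrays, although the gene was detected on 2 ESC arrays by its others, and all 3 probes rose. The thiolase gene Acaa2 fell (-3.37, adjusted p = 1.3e-08, all 4 probes lower). The transcription factor genes Satb1 (3.07), Lmo4 (3.22) and Wt1 (at least 8.43-fold) rose, the brain creatine kinase gene Ckb (-3.99) and the protease gene Mme (at least 11.03-fold) fell, with adjusted p-values of 8.8e-07, 3.3e-08, 3.1e-07, 1.7e-10 and 1.5e-08.

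The rise of the stromal markers Acta2, Thy1 and Dcn might come from fibroblasts or other stromal cells in the N2B27 48 hr cultures, although the labels describe growth without feeders. Of 4 probes of the abundant fibroblast collagen genes Col1a1, Col1a2 and Col3a1, 0 were detected on any N2B27 48 hr array. In all, 10 of the 14 fibroblast markers, these collagen genes among them, were detected on none of these arrays. This cannot exclude stromal cells, since the collagen probes were detected on 0 ESC arrays too and nothing here shows that they can detect their genes. A rise of serum response factor targets in the stem cells themselves is another candidate explanation, tested on a list written before its values were seen. It held only genes not looked at until then, so Acta2, Zyx and Egr1, already seen to rise, were left off. It therefore does not speak for every target of this factor. That list gave a camera p of 0.6128, with 3 of 12 members higher (Pdlim7, Tuft1 and Wdr1), 3 lower and a median of -0.066. The bound written beforehand counted any p of 0.05 or more against the idea, which is too easily met to exclude it. Members went both ways, and a p that misses the threshold excludes nothing. The idea stays open, as do stromal cells and a direct change of these genes on replating. No test here addresses the last.

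Under median scaling 29.7% of the changed genes rose, against 52.6% after quantile normalization, and the dim array N2B27 48 hr replicate 1 is a candidate cause. Without that array median scaling gave 45.19%. Leaving out each other array instead gave 22.9% to 35.4%. This is consistent with a weight of that array in the split, while the remaining gap to quantile normalization, and whether the amount of RNA per cell changed, stay open.

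Hox genes had a median log2 change of -0.31, at percentile 1.2 of 10000 random lists matched on mean log2 signal (the central 95% from -0.27 to 0.16). That comparison decides nothing about a shift of all dim probes, because 8 of the 13 Hox genes tested were detected on ESC arrays alone, so the change itself helped decide which were tested, and without the detection filter the median of the Hox genes with a probe was -0.0067.

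Genes that neighbour each other on a chromosome may change together in this comparison. Over 4282 pairs of adjacent protein-coding genes with different name stems, the log2 changes correlated with a Spearman's rho of 0.1646 (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give), across genes, which are not independent replicates. In 956 pairs where both changed, 65.4% went the same way, against 50.1% by chance, and rho was 0.096, 0.056, 0.023, 0.038 and 0.011 at 2, 3, 5, 10 and 50 genes apart, so it did not fall evenly. A trend of the change on signal level shared by neighbours was tested as a technical cause, and after its removal rho was 0.1669. Overlapping transcripts, probes that catch a neighbour's transcript and shared regulation remain open and were not tested.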
